A study of Homo sapiens with 13 samples.

How the data were processed

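The data are peak lists of EZH2 CUT&RUN, in which an antibody tethers a nuclease to chromatin and the released DNA is sequenced. Of the 13 samples, 12 are EZH2 libraries of HEK293T cells, a human embryonic kidney line, in 4 groups of 3, and each has its own list. The other is an IgG control, which was not used here. Per the labels' protocols, all cells were transfected with plasmids encoding aptamers and kept in 50 µM Ac5S, an inhibitor of the O-GlcNAc transferase OGT, for 20 h. From 20 h after transfection they were in fresh medium (Wnt-) or in medium containing 50% Wnt3A-conditioned medium (Wnt+), and nuclei were taken at 24 h after transfection. No group had conditioned medium without Wnt3A, so Wnt3A cannot be told apart from conditioned medium. Below, with and without Wnt3A stand for these media. Per the labels' protocols, each reaction used 500 ng of EZH2 antibody, and 0.12 ng of E. coli DNA was spiked in.

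The submitters' processing notes name Trim Galore, Bowtie2, SAMtools, bedtools, SEACR, DiffBind and ChIPseeker, without versions, and the builds GRCh38.p13 and ASM584v2 of E. coli. The names of the deposited lists carry the label of the IgG sample and the word stringent, which point to peaks called by the authors against that sample in the caller's stringent mode; the notes state neither. Each deposited list gives, for a peak called by the authors in that library, its position, the total signal over the peak, the highest signal, and the region of the highest signal. The values of both signal columns are the authors' scaled coverage. Within a library all values of the highest signal were whole multiples of 1 step, to within 0.000306 of a whole number. The total signal was not checked in this way. The step differed from 1.61 to 10.2 between libraries, so each library was scaled by its own constant. What the constant was taken from is not given in the sources used here. The lists hold no read counts, so the sequencing depth is unknown and no counting interval is given. The lowest total signal was 7449 to 7452 in the 3 lists of individual aptamers with Wnt+ medium and 5876 to 6701 in the other lists. Signal was therefore used mainly to rank peaks within a list, and lists were compared mainly by the presence or absence of peaks. Exceptions are the settings with the same lowest signal in all lists, scaled or in steps, and the signal values described per library.

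Peaks on chromosomes 1 to 22, X and Y were kept, 150056 over the 12 lists. Gene positions came from a RefSeq gene table of GRCh38.p14, which shares its chromosome sequences with GRCh38.p13. The table gives no strand. The planned window around the 5' end of each gene was therefore replaced by windows of 2 kb on both sides of either end of each of 20037 protein-coding genes, and a peak was near a gene end if it overlapped a window by at least 1 bp. As a check, 25.6% to 76.4% of a library's peaks lay near a gene end, against 7.30% to 9.00% when gene positions were moved by 1 Mb. Gene ends that share a window share their peaks.

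For each library the number of peaks (log2), the share of peaks near a gene end, the median peak width (log2) and the genes with a peak near an end were computed. Pairs of groups were compared with exact two-sided permutation tests of the difference of means, in which 3 libraries against 3 give 20 relabellings and no p below 0.1. Pooled comparisons permuted labels within the other factor (400 relabellings, smallest p 0.005). The interaction of aptamer and medium permuted the medium within each aptamer. Genes with a peak in 2 to 10 libraries were tested for each pooled comparison with an exact stratified test and Benjamini-Hochberg adjustment at 0.05. Genes with a peak in all 3 libraries of a group and none of the other group were counted. Of genes with a peak in exactly 3 of 6 libraries, 10% separate so on the mean over the 10 splits into 3 and 3. A single split can lie far from this mean where lists differ in length, so the mean is no test. Similarity of peak sets was the Jaccard index in bases, tested one-sided over all splits of the 12 libraries into 4 groups of 3. Replicates are separate samples in the labels, and nothing says that they came from separate cultures on separate days, so p-values measure the spread between these samples, which may be technical.

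The groups, comparisons, tests, alternatives, rule for named genes and 14 gene lists (778 genes, all 778 matched) were fixed before the data were examined. The lists were HOX cluster genes, other developmental transcription factors, Wnt/beta-catenin target genes, Wnt ligands, receptors and secreted inhibitors, BMP, TGF-beta, FGF and hedgehog ligands, clustered protocadherins, neurotransmitter receptors and neuronal channels, Polycomb complex subunits, O-GlcNAc and hexosamine pathway genes, cytosolic ribosomal proteins, proteasome and translation factors, lymphocyte and myeloid surface genes, keratin and olfactory receptor genes, and cell cycle inhibitors. The lists share no gene. Each list was given a log2 odds ratio per library of a peak in its members against all other genes, with 0.5 added to each cell. Its mean over 12 libraries was tested with exact sign flips (smallest p 0.000488), and its differences with the pooled test, adjusted over the lists. The named genes were the 10 genes with peaks in all 12 libraries and the highest mean percentile of total signal, up to 5 separating genes per pair of groups and direction, the 10 genes of smallest p per pooled comparison and direction, up to 4 members of each list with peaks in the most libraries, and EZH2, OGT, OGA, CTNNB1, AXIN2, LEF1, MYC, CCND1, CDKN2A, HOXA9 and HOXD13 whatever their values. Some named by the rule are left out below where their values repeat those of a neighbour, and some are not reported here.

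The gene test was tested on simulated data for dual against individual aptamers over both media. Of 200 genes simulated as changed among 10421 tested, 98.5% had an unadjusted p under 0.05 and 0% passed after adjustment, so the design could not call single genes at this share of changed genes. Peak and gene overlaps were checked against bedtools, with 82 of 82 pairs found by both. The same results were also computed with the same number of peaks per library (the 1937 of highest total signal, as many as the shortest list holds), the upper 50% of each list by total signal, peaks of at least 500 bp, windows of 1 kb and 5 kb, 50% of the peak inside the window, peaks within 1 kb merged, bases covered, other sets of chromosomes, other similarity measures, shares in place of odds ratios, each library left out in turn and the replicate number as a block. Alternatives added after the data were examined are named as such in the closing section. Among them, the same lowest signal in steps in all lists takes its cutoff from replicate 1 of individual aptamers in Wnt+ medium. It leaves 157 to 1937 peaks per library. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.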

Results

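EZH2, the methyltransferase subunit of a Polycomb repressive complex, was mapped by CUT&RUN in HEK293T cells in which OGT, the enzyme that adds O-GlcNAc to proteins, was inhibited with Ac5S. The cells expressed either individual aptamers as the control or a dual-specificity aptamer that, per the series title, raises O-GlcNAc on beta-catenin, the transcriptional effector of canonical Wnt signalling. Each aptamer was tested without Wnt3A (Wnt-) and with Wnt3A-conditioned medium (Wnt+), with 3 libraries per group. The lists held 13017 to 20191 peaks with individual aptamers in Wnt- medium, 3870 to 38900 with the dual aptamer in Wnt- medium, 1937 to 5304 with individual aptamers in Wnt+ medium and 3797 to 24009 with the dual aptamer in Wnt+ medium. Read numbers were not part of the lists, so the yield of a library could be described only from its peaks. The median over peaks of the highest signal was 18 steps in individual Wnt+ replicate 1, the shortest list, and 5 to 8 steps in the other libraries. List length is therefore not a full measure of yield, and most peaks rest on few steps.

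A peak lay near an end of 736 of the 20037 genes in all 12 libraries, and of 435 genes when each library was held to its 1937 strongest peaks. The region of highest mean rank, at chromosome 9, 137164426 to 137170982 (GRCh38), lay at GRIN1, the obligate subunit of NMDA receptors, and its neighbours LRRC26 and TMEM210, with a mean percentile of total signal of 99.97 within the 12 lists. Next came ADGRB1, a brain adhesion receptor (99.96), TMEM132E (99.95), FGF3, a fibroblast growth factor (99.91), VSTM2B (99.90), TENM4, a teneurin of neuronal wiring (99.88), PGR, the progesterone receptor (99.87), and C11orf96 (99.83). The FGF3 region lay at chromosome 11, 69816628 to 69820151, and the TENM4 region at chromosome 11, 79436346 to 79442064. Over all lists merged there were 86611 regions, of which 853 were found in all 12 libraries and 80.1% in 1 library only. Of the regions found in 12 libraries, 81.2% lay near a gene end, against 11.9% of the regions found in 1.

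Among the lists fixed in advance, 5 lists of developmental, neuronal and signalling genes had EZH2 peaks more often than other genes in 12 of 12 libraries. Of 161 developmental transcription factors outside the HOX clusters, 55.8% ± 14.5 (SD, n = 12) had a peak, a log2 odds ratio of 2.17 ± 0.32 against all other genes. NKX6-2, NEUROD2, PRDM12 and GSX1, regulators of neural differentiation, had peaks in all 12 libraries, as did 38 members in total. Neurotransmitter receptors and neuronal channels had a log2 odds ratio of 2.18 ± 0.44, with 20 of 65 members bound in all 12 libraries, among them GRIN1, GRM8, GRIK3 and the potassium channel gene KCNA1. For Wnt ligands, receptors and secreted inhibitors it was 1.93 ± 0.48, with 14 of 45 members bound throughout, including WNT7A, RSPO3, FZD8 and SFRP5. For Wnt/beta-catenin target genes it was 1.52 ± 0.21, with 5 of 43 members bound throughout, among them NOTUM, ASCL2, NKD2 and BAMBI, which include feedback inhibitors of the pathway. For BMP, TGF-beta, FGF and hedgehog ligands it was 1.51 ± 0.53, with FGF3, SHH, BMP2 and GDF7 bound in 12 libraries. Each of these 5 lists had an exact sign-flip p of 0.000488, the smallest possible, and an adjusted p of 0.000684. For these lists and those below, this p measures how consistently the 12 libraries of 1 cell line repeat a difference. It does not test a list against random lists of the same size, which matters most for the short lists.

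Cell cycle inhibitors also stood above other genes in 12 of 12 libraries (log2 odds ratio 0.95 ± 0.39, adjusted exact p = 0.000684; 0.57 among equal numbers of peaks), led by CDKN1C with peaks in 12 libraries and by GADD45G and GADD45A with peaks in 9. O-GlcNAc and hexosamine pathway genes were above in 10 of 12 libraries (0.67 ± 0.68, adjusted exact p = 0.00627; 0.37 with the whole gene span, adjusted exact p = 0.0947), with UAP1 and UAP1L1, which make or resemble the enzyme of UDP-GlcNAc synthesis, bound in 10. Polycomb subunit genes were above in 9 of 12 (0.36 ± 0.53, adjusted exact p = 0.0431), with BMI1 bound in 11; the difference was absent among equal numbers of peaks (-0.0072) and passed in only 3 of 12 settings with 1 library left out. HOX cluster genes did not differ from other genes (0.13 ± 0.60, above in 6 of 12 libraries, adjusted exact p = 0.456), although HOXA13 and HOXC13 had peaks in 12 libraries. Genes active in most cells were bound less often than other genes, with -1.21 ± 1.01 for cytosolic ribosomal proteins (adjusted exact p = 0.000684) and -0.83 ± 0.91 for proteasome and translation factors (adjusted exact p = 0.00249), the latter -0.34 with windows of 5 kb (adjusted exact p = 0.0737). The 2 lists had -2.87 and -1.79 among equal numbers of peaks. So were genes of other lineages, with -2.69 ± 1.15 for lymphocyte and myeloid surface genes and -2.28 ± 0.41 for keratin and olfactory receptor genes (both adjusted exact p = 0.000684, below in 12 of 12 libraries). Clustered protocadherins had -2.75 ± 0.80 (adjusted exact p = 0.000684), with PCDHAC1 the only member bound in 12 libraries. Members of this family share gene ends, and with the whole gene span in place of its ends their value was 0.75 (adjusted exact p = 0.0404), the opposite direction.

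**Figure D1:**
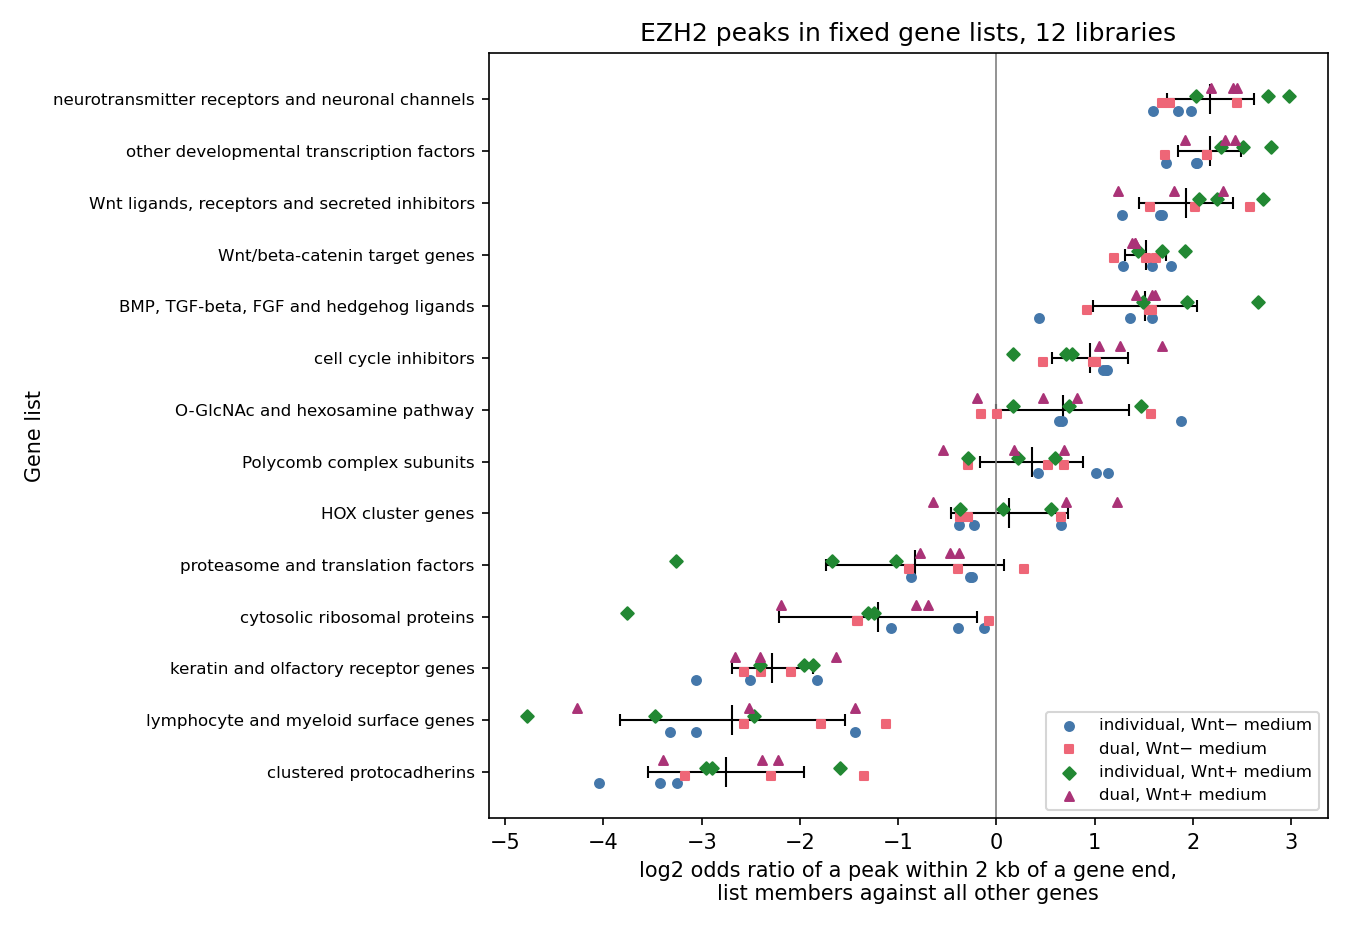
Log2 odds ratio of an EZH2 peak within 2 kb of a gene end in members of each of 14 gene lists against all other genes (horizontal axis), by list (vertical axis). Symbols are the 12 libraries by aptamer and medium, and black bars are mean ± SD over 12 libraries; developmental transcription factors lie at 2.17 ± 0.32 and keratin and olfactory receptor genes at -2.28 ± 0.41.

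Of the genes named in advance, AXIN2 and CCND1, targets of beta-catenin, had a peak near an end in 11 of 12 libraries each, and MYC in 9. EZH2 and OGA, the enzyme that removes O-GlcNAc, had a peak in 3 libraries each. OGT, LEF1, HOXA9 and CTNNB1, the gene of beta-catenin, had a peak in 1 library each, HOXD13 in 4 and CDKN2A in none. These counts depend on the window and the list. With windows of 5 kb HOXA9 had a peak in 6 libraries, HOXD13 in 7, OGA in 5 and MYC in 11. With windows of 1 kb CCND1 had a peak in 6, and with the whole gene span LEF1 in 3. Among equal numbers of peaks AXIN2 had a peak in 7, CCND1 in 8, MYC in 6 and EZH2, OGA and HOXD13 in 0. With the same lowest signal in steps in all lists AXIN2 and MYC had a peak in 4 libraries each and CCND1 in 1. AXIN2 was bound in 3 of 3 libraries of 3 groups and in 2 of 3 with the dual aptamer in Wnt- medium. CCND1 was bound in 3 of 3 libraries of 3 groups and in 2 of 3 with individual aptamers in Wnt+ medium.

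The first comparison asked whether the dual aptamer changes where EZH2 is found in cells without Wnt3A. The lists hold no measure of O-GlcNAc on beta-catenin, which per the series title this aptamer raises. FOXM1, a transcription factor of mitotic genes, AKT1S1, an inhibitor of mTOR signalling, CFAP43, SCUBE3 and CORIN were bound in 3 of 3 dual and 0 of 3 individual libraries, and they were the leading 5 of 13 such genes. In the opposite direction there were 235 genes, led by PHACTR2, the small GTPase gene RAP1B, AGTR1, an angiotensin receptor gene, NSMAF and CS, the citrate synthase gene. Of 2160 genes bound in exactly 3 of these 6 libraries, 11.5% separated by aptamer, where the mean over splits is 10%. Among equal numbers of peaks the counts were 11 and 36, and none of the genes named here separated. FOXM1 and AKT1S1 were also bound in 0 of 3 dual libraries in Wnt+ medium. With 1 library left out the counts were 15 to 118 and 269 to 1088. They can only stay or rise there, since fewer libraries must meet the rule. With the same lowest signal in steps in all lists they were 0 and 15. The dual libraries had 0.55 times as many peaks on the geometric mean (9497 against 17311, log2 ratio -0.87, exact permutation p = 0.4, n = 3 each; -1.88 to -0.22 with 1 library left out), a difference within the spread of the dual libraries, whose lists differed 10.1-fold in length.

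In Wnt+ medium, DLX3, a homeobox gene, IMPA2, NXPH4, the metabotropic glutamate receptor gene GRM3 and SAMD5 led 117 genes bound in 3 of 3 dual and 0 of 3 individual libraries. LETM1, HRAS and CAMTA1 were the 3 genes with the opposite pattern. Of these 8 named genes, IMPA2, NXPH4 and HRAS were bound in 3 of 3 libraries of both groups in Wnt- medium. Of 1113 genes bound in exactly 3 of the 6 libraries, 10.8% separated by aptamer, where the mean over splits is 10%. Among equal numbers of peaks the counts were 10 and 17, so the excess of genes bound with the dual aptamer was absent there. The dual libraries had 2.60 times as many peaks (log2 ratio 1.38, exact permutation p = 0.3, n = 3 each). The log2 ratio was 0.70 to 2.03 with 1 library left out. It turned to -0.60 with the same lowest signal in steps in all lists (exact permutation p = 0.4).

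Over both media, no gene separated the 6 dual from the 6 individual libraries, although 1 did with 50% of the peak required inside the window and 1 with the same lowest signal in steps. CORIN, which encodes a protease of natriuretic peptide processing, was bound in 6 of 6 dual and 1 of 6 individual libraries, and LCNL1 and the phosphatase gene PTPN1 in 5 of 6 and 0 of 6. ADAM23, the deacetylase gene SIRT1 and RPN1 were bound in 0 of 6 dual and 5 of 6 individual libraries. Held to equal numbers of peaks, CORIN, LCNL1 and PTPN1 had a peak in 1 dual library each, and SIRT1 and RPN1 in 0 libraries. ADAM23 then had a peak in 1 individual Wnt- and 2 individual Wnt+ libraries. These 6 genes had the smallest exact p, 0.02, among 9175 tested, and 0 genes passed after Benjamini-Hochberg adjustment (adjusted p = 1 for each). Next by p were SLC22A5, APAF1, a gene of the apoptosome, with its neighbour IKBIP, LRATD2, EHBP1L1, ARHGAP21 and CFAP43 for the dual aptamer and REEP4, NAAA, CRACD, HPD with its neighbour PSMD9, TESK1 and the thymidylate synthase gene TYMS for the individual aptamers (unadjusted exact p = 0.05 each). No list of genes differed by aptamer after adjustment over the 14 lists, and 0 of their members passed whether adjusted over all genes or adjusted over the list alone. For Wnt/beta-catenin target genes the log2 odds ratio was 0.19 lower with the dual aptamer, a difference of -0.19 (exact permutation p = 0.14, adjusted p = 0.62), and 0 of 24 members tested had an unadjusted p under 0.05.

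Wnt3A-conditioned medium was then compared with fresh medium in cells with individual aptamers, a comparison that cannot set Wnt3A apart from conditioned medium. MXRA8, PPFIBP2, CXXC5, a regulator of Wnt signalling, SPATC1 and the LIM homeobox gene ISL1 led 769 genes bound in 3 of 3 Wnt- and 0 of 3 Wnt+ libraries, and 0 genes had the opposite pattern. These 769 were 44.5% of the 1728 genes bound in exactly 3 of the 6 libraries, where the mean over splits is 10%. SPATC1 did not separate with windows of 1 kb or 5 kb (a difference of 0 libraries in both), and the merged region at it had peaks in 11 of 12 libraries, as that at MXRA8 had in 8. MXRA8 and CXXC5 were bound in 3 of 3 Wnt- and 0 of 3 Wnt+ libraries also among equal numbers of peaks. In that setting 27 genes were bound only in the Wnt- libraries and 21 only in the Wnt+ libraries. The 3 Wnt+ lists were shorter than all 3 Wnt- lists, with 3606 against 17311 peaks on the geometric mean (log2 ratio -2.26, exact permutation p = 0.1, the smallest that 3 against 3 allow). All 3 Wnt+ lists also began at a higher lowest total signal than any other list, and with the same lowest total signal in all lists 449 genes separated. With the same lowest signal in steps, 8 genes were bound only in the Wnt- libraries and 1 only in the Wnt+ libraries. With 1 library left out, where counts can only stay or rise, they were 809 to 1614 and 0 to 14.

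With the dual aptamer, RAP1B, CDK5R1, an activator of the kinase CDK5, RAB39A, NXT1 and ZNF555 led 37 genes bound in 3 of 3 Wnt+ and 0 of 3 Wnt- libraries, and CCDC183, RNASEK with its neighbour BACC1, and OPN3 with its neighbour CHML led 45 genes of the opposite pattern. Of 1757 genes bound in exactly 3 of these 6 libraries, 4.67% separated by medium, where the mean over splits is 10%. With 1 library left out, where counts can only stay or rise, 44 to 257 genes were bound only with Wnt3A and 57 to 368 only without it. With the same lowest signal in steps in all lists the counts were 1 and 0. The numbers of peaks were not shown to differ (9375 against 9497 on the geometric mean, log2 ratio -0.019, exact permutation p = 0.9, n = 3 each). The change with medium was not shown to differ between the aptamers, with an interaction of 2.25 on the log2 scale (exact permutation p = 0.175, 12 libraries). Without the dual Wnt- library of 38900 peaks, replicate 3, the interaction was 3.26 (exact permutation p = 0.025).

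Over both aptamers, CCDC183, TIGD7 and FNTA, which encodes a farnesyltransferase subunit, were bound in 6 of 6 Wnt- and 0 of 6 Wnt+ libraries (exact p = 0.005, the smallest possible, adjusted p = 1). For CCDC183 the difference with the dual aptamer was 1 library in place of 3 with windows of 5 kb or the whole gene span. Held to equal numbers of peaks, CCDC183 had a peak in 2 dual Wnt- libraries only, TIGD7 in 1, and FNTA in 0 libraries. Of 9175 genes tested, 72 had an unadjusted exact p under 0.05, all bound in fewer Wnt+ libraries, and 0 passed after adjustment. They included the nucleoporin gene NUP98 with its neighbour PGAP2, CCDC85C with its neighbour HHIPL1, MTUS1 and CUL1, a ubiquitin ligase scaffold. Genes bound in more Wnt+ libraries had p values of 0.1 or more, led by THSD7A at 0.1 and by HTR2C, ADAMTS12, KIF1A, CNTN3, MIER3 and GCLC, each bound in 6 of 6 Wnt+ and 3 of 6 Wnt- libraries (exact p = 0.2). Among equal numbers of peaks 7 genes had an unadjusted p under 0.05, of which 5 were bound in more Wnt+ libraries. Developmental transcription factors had a log2 odds ratio 0.41 higher in Wnt+ medium (exact permutation p = 0.02, adjusted p = 0.21) and neurotransmitter receptors and channels 0.58 higher (exact permutation p = 0.03, adjusted p = 0.21). The differences were 0.22 and 0.15 among equal numbers of peaks. No list passed after adjustment, and for Wnt/beta-catenin target genes the difference was 0.045 (exact permutation p = 0.71, adjusted p = 0.765).

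**Figure D2:**
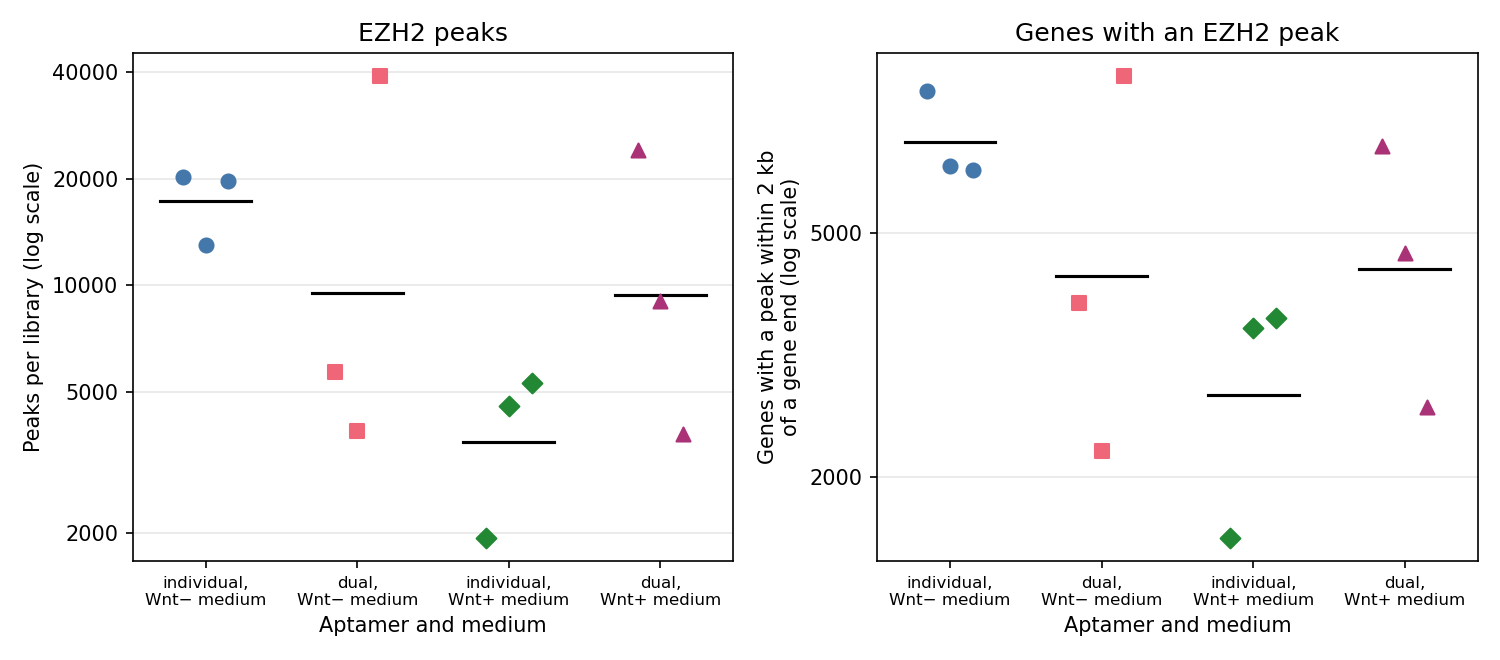
Number of EZH2 peaks per library (left, log axis) and of genes with a peak within 2 kb of an end (right, log axis) by aptamer and medium (horizontal axis). Points are the 3 libraries of each group and lines their geometric mean; the 3 libraries of individual aptamers in Wnt+ medium hold 1937, 4564 and 5304 peaks.

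Peaks near gene ends made up 41.5% ± 8.20 (SD, n = 3) of the lists with individual aptamers in Wnt- medium, 48.4% ± 20.1 with the dual aptamer in Wnt- medium, 70.9% ± 6.45 with individual aptamers in Wnt+ medium and 48.9% ± 18.5 with the dual aptamer in Wnt+ medium. With individual aptamers the share was 29.4 percentage points higher in Wnt+ medium (exact permutation p = 0.1), and pooled over aptamers 14.96 points higher (exact permutation p = 0.15). With the same lowest signal in steps in all lists both turned, to -2.27 points (exact permutation p = 0.1) and -1.83 points (exact permutation p = 0.02). The share followed the length of the list, with a Pearson r of -0.948 over 12 libraries (permutation p = 1e-05, the smallest that 100000 permutations give, adjusted p = 2.5e-05) and a Spearman rho of -0.930 (permutation p = 0.0001, adjusted p = 0.000425), 1 of 5 relations computed. It held within groups (r = -0.925) and without the dual Wnt- replicate 3 and the individual Wnt+ replicate 1 (r = -0.914). Among the 1937 strongest peaks of each library the 4 groups had means of 74.2% to 77.0%, and the difference with medium for individual aptamers was -0.034 points.

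**Figure D3:**
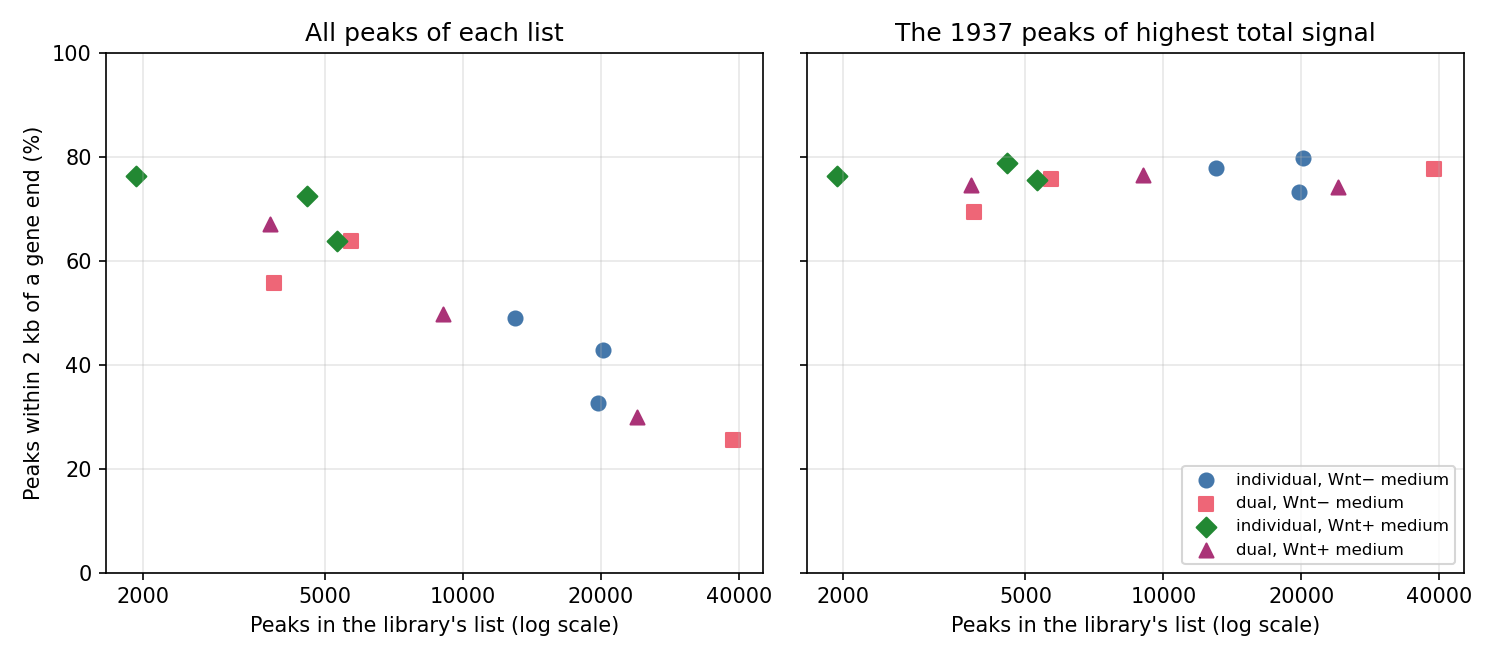
Share of EZH2 peaks within 2 kb of a gene end (vertical axis, percent) against the number of peaks in the library's list (horizontal axis, log scale), for all peaks (left) and for the 1937 peaks of highest total signal in each library (right). Each point is 1 of 12 libraries; the share spans 25.6% to 76.4% on the left and 69.3% to 79.8% on the right.

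Over all peaks of each list, peaks were narrower with the dual aptamer and wider in Wnt+ medium, but both differences depended on the peaks compared. With the same lowest signal in steps in all lists they turned, to log2 differences of 0.051 (exact permutation p = 0.435) and -0.050 (exact permutation p = 0.455). Neither passed with the same lowest total signal (exact permutation p = 0.125 and 0.08). The median width was 598 ± 10.8 bp (SD, n = 3) with individual aptamers and 540 ± 42.4 bp with the dual aptamer in Wnt- medium, and 921 ± 349 bp and 608 ± 31.4 bp in Wnt+ medium. Pooled over media, the dual aptamer gave 0.79 times the width (log2 difference -0.34, exact permutation p = 0.02), and pooled over aptamers Wnt+ medium gave 1.29 times the width (log2 difference 0.36, exact permutation p = 0.015). With 1 library left out, each difference passed in 9 of 12 settings. Neither difference passed among equal numbers of peaks, where they were -0.28 (exact permutation p = 0.23) and 0.0094 (exact permutation p = 0.97). The median width followed the lowest total signal of the list counted in steps (Pearson r = 0.971 over 12 libraries, permutation p = 1e-05, adjusted p = 2.5e-05). The Spearman rho was 0.902 (permutation p = 0.00017, adjusted p = 0.000425). Pearson r was 0.937 within groups, and 0.874 without dual Wnt- replicate 2 and individual Wnt+ replicate 1. Total signal is summed over the bases of a peak and so contains its width, and part of this relation was fixed in advance.

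Libraries of the same group were not shown to share more of their peaks than libraries of different groups. The Jaccard index was 0.187 ± 0.0900 (SD, 12 pairs) within groups and 0.170 ± 0.0619 (54 pairs) between groups, a difference of 0.0173 (exact one-sided permutation p = 0.114). Among equal numbers of peaks it was 0.357 within and 0.354 between groups. The individual Wnt+ libraries had the highest index within a group, 0.313 ± 0.0183 (3 pairs), and the dual Wnt- libraries the lowest, 0.106 ± 0.0688; among equal numbers of peaks the individual Wnt- libraries were highest (0.405 against 0.395 for individual Wnt+). This depended on single libraries, from -0.0051 without individual Wnt+ replicate 1 to 0.034 without dual Wnt- replicate 1 (exact one-sided permutation p = 0.0339).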

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

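The tests of calling thresholds, scaling and equal numbers of peaks as explanations were chosen after the results were seen; the counts of other splits were planned.

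Cell cycle inhibitor genes stood out because the change of their log2 odds ratio with medium differed between aptamers. It was 1.07 higher with the dual than with the individual aptamers (exact permutation p = 0.005, the smallest possible, adjusted p = 0.07 over the 14 lists), from -0.56 with individual aptamers to 0.50 with the dual aptamer. The list has 16 genes, and CDKN1B was bound in 3 of 3 individual Wnt- and 0 of 3 individual Wnt+ libraries and in 2 of 3 and 3 of 3 dual libraries, but among equal numbers of peaks in 1 library only. The result does not pass after adjustment. Among equal numbers of peaks the group means were 0.43 and 0.65 with individual aptamers (Wnt-, Wnt+) and 0.22 and 1.00 with the dual aptamer, so the direction with individual aptamers was turned.

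Peaks also lay outside chromosomes 1 to 22, X and Y, on sequences that no comparison used. There were 370 of them on 33 sequences, 0.246% of all peaks, with 12 to 68 per library, and 143 lay on a single sequence that had a peak in 12 of 12 libraries. No control list was used here, so the background on these sequences is not known.

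The shorter lists with individual aptamers in Wnt+ medium are a pattern of peak number and of bound genes. The real split separated 769 genes, all bound only without Wnt3A, against at most 242 for another split of the 6 libraries. With 10 splits no share can be under 0.05. The higher lowest total signal of these 3 lists, in scaled units, did not account for the whole difference. With the same lowest total signal in all lists the log2 ratio was -1.73, beyond the group's SD of 0.78, against -2.26 before. Each library has its own scaling constant, so this cannot exclude a higher calling threshold in unscaled steps. With the same lowest signal counted in unscaled steps the log2 ratio was -0.019, so scaling could account for the difference. That cutoff was set by individual Wnt+ replicate 1, which keeps all its 1937 peaks, while the other libraries keep 157 to 1703. Unscaled steps may also vary with sequencing depth, which is unknown. But these 3 libraries are also the 3 whose lists start at the most steps, so scaling and group cannot be told apart. Among equal numbers of peaks, chosen by rank and so free of the scaling, 21 and 27 of 319 genes separated. A response of EZH2 to Wnt3A-conditioned medium stays open, and Wnt3A cannot be told apart from conditioned medium.

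The lower share of peaks near gene ends in longer lists may reflect weak peaks that only the longer lists reach. Over the 1937 strongest peaks per library the correlation with list length was 0.233, against -0.948 with all peaks. This was a test that could have kept the relation, and the relation was absent among the strongest peaks. With all peaks it also held within groups (r = -0.925), where aptamer and medium are the same. The test cannot set list length against medium, since all individual Wnt+ lists were shorter than all individual Wnt- lists. No biological explanation was tested.

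The narrower peaks with the dual aptamer and wider peaks in Wnt+ medium may come from the scaling too. With the same lowest signal in unscaled steps, the log2 differences of median width were 0.051 for the dual aptamer (exact permutation p = 0.435) and -0.050 for Wnt+ medium (exact permutation p = 0.455), so neither kept its direction. That setting is set by the individual Wnt+ replicate 1, whose list starts at 4631 steps, and it leaves 157 to 1937 peaks per library. Without that library and the dual Wnt- replicate 3 the differences were -0.23 (exact permutation p = 0.02) and 0.25 (exact permutation p = 0.01), and without single libraries each passed in 9 of 12 settings (largest exact permutation p = 0.1 and 0.09).

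Other splits of the libraries bear on the counts of genes. For the dual against the individual aptamers, 3 of 10 splits separated at least the 248 genes of the real split in Wnt- medium (highest other 655) and 4 of 10 at least the 120 in Wnt+ medium (highest other 265). For medium, 1 of 10 splits, the real split itself, reached the 769 genes with individual aptamers and 7 of 10 reached the 82 with the dual aptamer (highest other 620). These splits are too few for a share under 0.05. Over both strata, 70 of 100 splits gave at least the 6 genes of unadjusted p under 0.05 for the aptamer (highest other 223), and 10 of 100 gave at least the 72 for medium (highest other 349), so chance cannot be excluded for either.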

How the results depend on the processing

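Most values kept their direction and their side of the threshold (counts of genes stayed within 1.5 times, and counts of libraries for single genes within 1), 427 of 492 with 1 library left out and 938 of 1105 in other settings. Part of this was fixed in advance, since 3 libraries against 3 give no p below 0.1 and cannot cross the threshold. Counts of separating genes stayed within 1.5 times less often. When libraries are left out these counts can only stay or rise, since fewer libraries must meet the rule. Their rise there is therefore no measure of stability. With 1 library left out, 6 of 24 counts of genes bound only with the dual aptamer or only with Wnt3A stayed within 1.5 times. For the opposite pattern 9 of 24 did. The settings with the same lowest total signal, the same lowest signal in steps, the whole gene span, and without the 2 libraries that stand apart were added after the results were seen. Any transcript start as a window was not run, since the gene table gives no transcripts. Where a direction or a call changed below, the cause was not tested except where named. All p-values in this part are from exact permutations.

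With the same lowest signal in steps, 0 and 15 genes separated for the dual aptamer without Wnt3A (bound only with it, bound only without it), 0 and 19 with Wnt3A, 1 and 8 for Wnt+ medium with individual aptamers and 1 and 0 with the dual aptamer. Differences in peak number were 0.35 for medium over both aptamers, 0.72 for medium with the dual aptamer, -0.60 for the dual aptamer in Wnt+ medium and -0.98 over both media. Median widths moved to -0.050 and 0.051 for medium and aptamer over both strata, -0.14 for medium with individual aptamers and 0.14 for the dual aptamer in Wnt+ medium. The share near gene ends moved to -1.83 points for medium over both aptamers (exact p = 0.02), -1.38 with the dual and -2.27 with individual aptamers, and 0.294 and -0.597 for the dual aptamer with and without Wnt3A. Polycomb subunits lost their call (0.19, adjusted exact p = 0.299). Similarity moved to -0.0044, ARHGAP21 to -0.17, Wnt/beta-catenin target genes to 0.15 for the aptamer and -0.46 for medium, and neurotransmitter receptors and channels to -0.015 for medium.

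With the same lowest total signal, 66 and 7 genes separated for the dual aptamer in Wnt+ medium and 449 were bound only without Wnt3A with individual aptamers. The widths lost their call, at 0.30 for medium (exact p = 0.08) and -0.27 for the aptamer (exact p = 0.125). With equal numbers of peaks, counts were 20 and 14 for medium with the dual aptamer, 21 and 27 with individual aptamers, and 10 and 17 for the dual aptamer in Wnt+ medium, with 36 genes bound only with individual aptamers in Wnt- medium. There the widths were 0.0094 for medium, -0.17 for medium with individual aptamers and -0.28 for the aptamer, and the share near gene ends -0.034 points for medium with individual aptamers and -2.74 for the dual aptamer in Wnt- medium. HOX cluster genes moved to -0.32 and Polycomb subunits to -0.0072, which ended the call of the latter.

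In the upper 50% of each list, 15 genes were bound only with Wnt3A with the dual aptamer, 73 and 0 separated for the dual aptamer in Wnt+ medium, and 3 were bound only with it in Wnt- medium. With the gene span, 1165 genes were bound only without Wnt3A with individual aptamers and 1 only with individual aptamers in Wnt+ medium, the share near genes was -1.44 points for medium with the dual aptamer, and log2 odds ratios were -0.064 for Wnt/beta-catenin target genes by medium, -0.0047 for HOX cluster genes and 0.75 for clustered protocadherins (adjusted exact p = 0.0404), and O-GlcNAc and hexosamine pathway genes lost their call (0.37, adjusted exact p = 0.0947). With windows of 5 kb, 0 genes were bound only with individual aptamers in Wnt+ medium, the share was -0.162 points for medium with the dual aptamer, and proteasome and translation factors lost their call (-0.34, adjusted exact p = 0.0737). With windows of 1 kb, Wnt/beta-catenin target genes had -0.024 by medium and HOX cluster genes -0.0055, and with shares of members the former had -2.76 points. By bases covered, and with peaks of at least 500 bp, the peak number differed by 0.18 and 0.26 for medium with the dual aptamer and by -0.087 and -0.030 for the aptamer over both media. Similarity by overlap coefficient was -0.016.

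Without individual Wnt+ replicate 1 and dual Wnt- replicate 3, 257 genes were bound only with Wnt3A with the dual aptamer, 14 with individual aptamers, 66 only with individual aptamers in Wnt+ medium and 1088 in Wnt- medium. Peak number then differed by 1.00 for medium with the dual aptamer and -0.48 for the aptamer over both media, with an interaction of 2.81 (exact p = 0.04), and the share near gene ends by -10.9 points for medium with the dual aptamer.

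With 1 library left out, peak number ranged from -1.88 to -0.22 for the dual aptamer in Wnt- medium, from 0.70 to 2.03 in Wnt+ medium, from -0.70 to 1.00 for medium with the dual aptamer, from -0.25 to 0.58 for the aptamer over both media and from 1.57 to 3.26 for the interaction (exact p = 0.025 at the latter). The share near gene ends ranged from -0.875 to 18.3 points for the dual aptamer in Wnt- medium and from -10.9 to 9.98 for medium with the dual aptamer. Widths ranged from -0.47 to -0.20 for the aptamer and from 0.22 to 0.49 for medium, and each kept its call in 9 of 12 settings (largest exact p = 0.1 and 0.09). Polycomb subunits ranged from 0.29 to 0.44 and kept their call in 3 of 12 (largest adjusted exact p = 0.0862). Genes bound only with the dual aptamer numbered 15 to 118 in Wnt- medium and 133 to 733 in Wnt+ medium, and only with individual aptamers 269 to 1088 and 3 to 66. Genes bound only with Wnt3A numbered 0 to 14 with individual and 44 to 257 with the dual aptamer, and only without it 809 to 1614 and 57 to 368. Wnt/beta-catenin target genes ranged from -0.021 to 0.10 by medium, and similarity from -0.0051 to 0.034.

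Replicate numbers were checked as a block. Of 12 pairs with the same number, 0 had a correlation of deviations over 0.1, and 1 of 12 libraries correlated best with its own number, so they were not treated as pairs. The block ended both calls of width, at -0.34 (exact p = 0.09375, aptamer) and 0.36 (exact p = 0.0625, medium), and left 0 genes called, with 0 and 3 at an unadjusted p under 0.05 in place of 6 and 72.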

Other observations

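All values in this part were looked for after the data were examined.

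EZH2 peaks away from gene ends were locally dense in some stretches of the genome. Over all 12 lists a stretch of 2 Mb held a median of 65 peaks. On chromosome 5, the stretch from 2000001 to 4000000 (GRCh38) held 1403 peaks, of which 3.06% lay near a gene end, and its annotated protein-coding genes are IRX1 and IRX2, homeobox genes of neural and limb patterning. It took 0.915% ± 0.246 (SD, n = 12) of a library's peaks, against a median of 0.0429% per stretch. On chromosome 9, the stretches from 134000001 to 136000000 and from 136000001 to 138000000 held 1751 and 2431 peaks. Of these, 13.1% and 43.3% lay near a gene end, so the latter stretch was dense at gene ends too. The 2 stretches contain OLFM1, COL5A1, NOTCH1, LHX3 and GRIN1. On chromosome X, the stretch from 22000001 to 24000000 held 1260 peaks, 6.83% of them near a gene end, with PTCHD1 and PHEX among its genes. On chromosome 10, the stretch from 130000001 to 132000000 held 784. These genes were named after their values were seen.

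By chromosome, 7.41% ± 1.86 (SD, n = 12) of a library's peaks lay on chromosome 9 and 8.63% ± 0.607 on chromosome 5, which hold 3.88% and 4.51% of the genes. The share on chromosome 9 ranged from 5.94% to 12.7% between libraries. Chromosome 10 took 6.18% ± 0.372 of the peaks with 3.66% of the genes. Chromosome 14 took 1.53% ± 0.203 of the peaks with 3.02% of the genes, chromosome 21 took 0.508% ± 0.0831 with 1.19%, and chromosome 19 took 4.41% ± 0.628 with 7.24%. Copy numbers of the chromosomes in these cells were not analysed here.

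The 6518 genes with no peak near an end in any library are 1 end of a wide distribution, with 3191 genes bound in 1 library only, 894 in 6 and 736 in all 12. Of the fixed lists, 45 of 53 clustered protocadherins, 42 of 64 keratin and olfactory receptor genes and 39 of 64 lymphocyte and myeloid surface genes had no peak in any library, against 14 of 161 developmental transcription factors and 6 of 43 Wnt/beta-catenin target genes. All 12 genes of the O-GlcNAc and hexosamine pathway had a peak in at least 1 library, and none had a peak in all 12.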
